A study of Cucumis sativus with 16 samples.

How the data were processed

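The study sequenced poly(A) RNA from the pericarp of 16 cucumber samples, with 1 paired-end library per sample. The labels place them in 8 groups of 2: own-rooted, self-grafted, grafted on rootstock 3212 and grafted on rootstock 3225, each without or with 1.7 mM silicon. The molecule field reads total RNA for 15 samples and poly(A) RNA for the first own-rooted sample without silicon, while the extraction text describes poly(A) selection for all. Read counts per gene model were taken from the authors' tables for single libraries, as whole numbers that sum to the total in the column header. The authors also gave RPKM values (reads scaled by gene model length and library total), which equal the counts divided by coding length and that total. The aligner, the counting rule, the genome build and the annotation are not given in the sources used here, so positions are not printed and the handling of reads shared between similar genes is unknown. Gene models without a read are not listed in a library's table and were set to 0. Names come from the description of the best protein hit in the authors' tables, which names a protein for 13429 of the 21255 gene models with a read; 1461 of these models lie at loci with more than 1 model.

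The library totals were 10663641 to 11387613 reads. At this depth counting error is small for genes of moderate abundance, and the spread between the libraries of a group sets the precision. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Gene models were kept by filterByExpr on the groups, which left 16953. Libraries were scaled by TMM, and a quasi-likelihood model with 1 mean per group was fitted to all 16 libraries, so that the 8 groups shared an estimate of the spread; the common dispersion was 0.0406. Each of 22 contrasts was tested two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05, and genes below it are called. The contrasts were the silicon effect in each graft type and on average, the differences between graft types without and with silicon, the least-bloom group against the dense-bloom groups, and differences in silicon response between graft types. The standard error of a log2 fold change was taken from the test statistic. Genes called in the same direction between 3212-grafted and self-grafted plants both without and with silicon were used, after the data were seen, to ask which of the 2 means each group lies nearer on log2 CPM. Principal components were computed on log2 CPM (counts scaled to library size, prior count 2).

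Genes were named by a rule. Its first part took the 6 highest and the 6 lowest log2 fold changes per contrast among called genes with a mean log2 CPM of at least 2, a description that names a protein, and every library of a group above every library of the other. For the average effect these genes had to move the same way in all 4 graft types, and for differences in response the condition on libraries was dropped. Its second part took from each gene list the 2 called members with the smallest p, without these conditions, and every silicon transport gene. Of the 113 pairs of gene and contrast in the text, 46 came from the first part and 65 from lists alone; of the 65, 5 lay below the abundance limit and 7 did not meet the condition on libraries or graft types, 10 in all. The 2 pairs outside the rule are marked where they occur, and so is NAC72, which was chosen after its values were seen. Gene lists were made from words in the protein descriptions. The 26 lists covered silicon transport, aquaporins, cuticle and wax, epidermis and trichome, cell wall, phenylpropanoid and lignin, flavonoids, photosynthesis, and heat shock and chaperones. They also covered redox, jasmonate, ethylene, auxin, abscisic acid, gibberellin, defence (pathogenesis-related and resistance proteins), WRKY factors, ABC transporters, mineral transport, and sucrose and raffinose. The rest were ribosomal proteins, cell cycle, clock and light, triterpene cyclases, phloem genes, and seed markers of another tissue. A gene may be in several lists. Lists with at least 5 tested members were tested with limma camera (3.58.1, two-sided) on log2 CPM with a preset inter-gene correlation of 0.01 and adjustment over the lists of a contrast.

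The groups, contrasts, lists, naming rule and most alternatives were fixed before the data were examined. These alternatives were RLE size factors, DESeq2 1.42.0 with its default filtering, no filter beyond 1 read, a filter on a mean count of 20, a fit of only the groups compared, the replicate number as a block, limma with trend on log2(RPKM + 1) and on log2(RPKM + 0.1), and leaving out each library of a contrast in turn. For the lists they were an estimated correlation, the replicate block, log2(RPKM + 1) and limma's fry with statmod 1.5.0. Chosen after seeing the data were the fits without the second own-rooted library lacking silicon for contrasts that do not use it and for the lists, the lists without members whose description names another function, and camera on 142 gene ontology process terms of 15 to 500 genes. Also chosen after seeing the data was an edgeR fit with library totals as the scale in place of TMM; a split in direction is printed where this fit or limma on log2(RPKM + 1) moved it by over 10 percentage points.

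The log2 ratio values in the authors' filtered tables compare single libraries of the same number and equal the log2 ratio of RPKM, with 0 replaced by a small constant. Their p-value and FDR columns were computed by the authors with a test that is not given in the sources used here; entries have an FDR of at most 0.001 and an absolute log2 ratio of at least 1, as checked on the values. For 13 contrasts the tables of both library numbers were compared with each other and with the calls, and a minimum of 2 was the alternative. Tables that set a supplied graft against an unsupplied group of another graft type were not used here, because they fall outside the contrasts; only their count columns were set beside the tables of single libraries. The edgeR, limma and DESeq2 tests were tested on simulated data of 16953 genes with 200 changed. The simulated libraries had the fitted dispersion in every group, and none stood apart from its replicate. For the silicon contrast in own-rooted plants edgeR recovered 42% of 2-fold and 93% of 4-fold changes with 9 false calls, DESeq2 44% and 93% with 17, and limma 19% and 85% with 4. Files were read and figures drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.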

Results

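The samples were pericarp, the fruit wall of cucumber (Cucumis sativus), whose surface can carry bloom, a whitish powder rich in silica. Messenger RNA was sequenced from 16 libraries in 8 groups of 2, formed by 4 graft types grown without or with 1.7 mM silicon. The graft types were own-rooted plants, self-grafted plants, and cucumber tops on the pumpkin rootstock lines 3212 and 3225, which the labels describe as a weak and a strong silicon absorber. Silicon was supplied as potassium silicate at flowering, and pericarp was collected 2 h after the addition. Potassium was therefore added with it, and no group received potassium alone. The labels give sparse bloom to every group without added silicon, dense bloom to the supplied own-rooted, self-grafted and 3225-grafted plants, and the least bloom to the supplied 3212-grafted plants. Each library held 10663641 to 11387613 reads in gene models, and 16953 of the 21255 gene models with a read were tested.

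The libraries of a group differed by more than sampling noise in all 8 groups, with a mean chi-square per gene of 7.9 to 80.2. Own-rooted plants without silicon had the least similar pair, with a correlation across genes of 0.93, against 0.972 to 0.989 in the 7 other groups. In that pair 602 genes differed at least 4-fold, against 30 to 192 elsewhere. The second library of the pair carried 206 CPM (counts scaled to library size) of the transcription factor NAC72 (Csa3M101810.1), against 2.67 CPM in the first. NAC72 was chosen after its values were seen. The first principal component held 34% of the variance and placed both libraries of a group on the same side in all 8 groups. The supplied own-rooted libraries lay on the side of the 3212-grafted and unsupplied 3225-grafted ones, and the supplied 3225-grafted libraries on the side of the self-grafted and unsupplied own-rooted ones. A set of 1478 genes was called in the same direction between 3212-grafted and self-grafted plants both without and with silicon. Of these, 92.3% lay nearer the self-grafted mean in own-rooted plants without silicon, but 8.1% in own-rooted plants with silicon. In 3225-grafted plants 84% lay nearer the 3212-grafted mean without silicon, but 4.7% with silicon. Nothing in the labels says that the libraries of a group came from separate plants, and if they did not, p-values measure only the spread between samples of the same plants. Genes with near-identical copies, such as the neighbouring PIP2 genes, the PIP1-4 pair and the lipoxygenases, are uncertain one by one, because how shared reads were counted is not given in the sources used here. Fold changes below are log2 values with their standard error from edgeR's quasi-likelihood test, adjusted p is the Benjamini-Hochberg value from that test, and each group mean rests on n = 2 libraries. The log2 changes refer to TMM scaling.

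**Figure D1:**
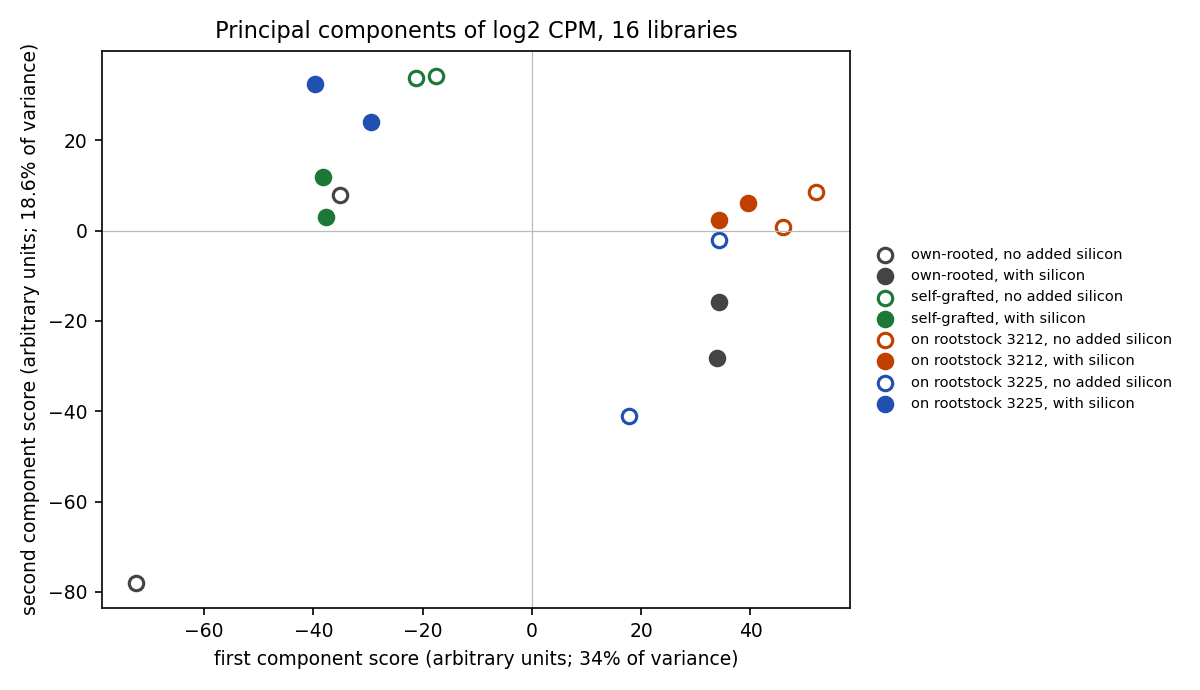
Scores of the 16 libraries on the first and second principal components of log2 CPM (arbitrary units; 34% and 18.6% of the variance). Colour gives the graft type, and open and filled symbols give no silicon and added silicon. On the first component supplied own-rooted libraries lie on the side of the 3212-grafted and unsupplied 3225-grafted ones. Supplied 3225-grafted libraries lie on the side of the self-grafted and unsupplied own-rooted ones. The second own-rooted library without silicon lies lowest, at -77.9 on the second component.

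The first comparison asked what silicon did on average over the 4 graft types. The heat shock and aquaporin lists were higher after silicon by camera with the preset correlation, and neither passed with an estimated one (adjusted p = 0.095 and 0.055). In own-rooted plants aquaporins were lower (14 of 31 called lower, 1 higher), and that list test did not pass with an estimated correlation either. Heat shock protein 83 (Csa3M183950.1), an HSP90-type chaperone, rose by 2.99 ± 0.45 (adjusted p = 0.0072) by edgeR. Heat shock cognate 70 kDa protein (Csa5M514500.1) rose by 2.65 ± 0.30 (adjusted p = 0.0026), and the protein disaggregase ClpB1 (Csa1M039100.1) by 2.25 ± 0.30 (adjusted p = 0.0044). The heat-response coactivator MBF1c (Csa2M004720.1) rose by 2.69 ± 0.55 (adjusted p = 0.033) and an 18.5 kDa small heat shock protein (Csa1M527870.1) by 2.32 ± 0.41 (adjusted p = 0.018). The heat shock and chaperone list had 23 of 150 higher and 1 lower (31 and 5 adjusted over the list alone), and 126 did not pass. As a list it was higher, with camera adjusted p = 2.3e-05, and adjusted p = 0.095 with an estimated correlation.

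Aquaporin PIP2-2 (Csa6M445140.1), a plasma membrane water channel, rose by 1.76 ± 0.11 (adjusted p = 1.4e-05) by edgeR, and PIP1-4 (Csa5M199270.1) by 1.22 ± 0.09 (adjusted p = 4e-05). The aquaporin list had 7 of 31 higher and 0 lower (7 and 1 adjusted over the list alone), with camera adjusted p = 0.00056, and adjusted p = 0.055 with an estimated correlation. Flavonoid synthesis genes were higher as a list, with 4 of 50 higher and 0 lower (11 and 1 adjusted over the list alone) and camera adjusted p = 1e-04, and adjusted p = 0.16 with an estimated correlation. Among them leucoanthocyanidin dioxygenase (Csa5M206420.1) rose by 1.28 ± 0.17 (adjusted p = 0.0044). Phenylpropanoid and lignin genes had 6 of 66 higher and 1 lower (17 and 2 adjusted over the list alone), with camera adjusted p = 5e-04, and adjusted p = 0.3 with an estimated correlation. The enzyme 4-coumarate-CoA ligase (Csa3M710200.1), which feeds lignin and flavonoid synthesis, rose by 0.65 ± 0.09 (adjusted p = 0.0045). Ribosomal protein genes were lower as a list (median -0.15 log2), with 2 of 251 lower and 1 higher (10 and 1 adjusted over the list alone) and camera adjusted p = 5.2e-06, and adjusted p = 0.63 with an estimated correlation. The trichome regulator GLABRA2 (Csa7M447000.1) rose by 0.70 ± 0.14 (adjusted p = 0.029) and potassium transporter 8 (Csa5M630840.1) by 1.22 ± 0.24 (adjusted p = 0.03). The sugar exporter SWEET10 (Csa1M001300.1) fell, at -3.57 ± 0.54 (adjusted p = 0.0079), as did the abscisic acid receptor PYL4 (Csa4M312880.1), at -1.18 ± 0.16 (adjusted p = 0.0045), and the antimicrobial peptide snakin-1 (Csa2M354910.1), at -1.20 ± 0.25 (adjusted p = 0.038). SWEET10 and potassium transporter 8 lay below the abundance limit of the naming rule.

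For 4 of these genes the group mean moved the other way in a graft type. From no silicon to added silicon, potassium transporter 8 went from 5.32 to 4 CPM in own-rooted plants, and heat shock cognate 70 kDa protein from 91.7 to 88.9 CPM in self-grafted plants. In 3225-grafted plants 4-coumarate-CoA ligase went from 27.9 to 25.2 CPM and PYL4 from 9.62 to 10.1 CPM. Libraries without and with silicon also overlapped for heat shock protein 83 and GLABRA2 in self-grafted plants, MBF1c in own-rooted plants, snakin-1 in own-rooted and 3225-grafted plants and potassium transporter 8 in 3225-grafted plants. In all, 260 genes were called for the average effect, 182 higher and 78 lower, by edgeR. The supplied own-rooted and 3225-grafted plants in it lay nearer the other kind of root in the set of 1478 genes. Both enter the average with the same weight, so an exchange of their group labels would leave these calls as they are. Leaving out 1 library gave 57 to 1249 genes and moved the count by over 1.5 times for 14 of the 16 libraries, all but the pair from supplied 3225-grafted plants; without the second own-rooted library lacking silicon it was 1041, and DESeq2 called 749. Of the 14 genes named for this effect, 9 kept their call whichever library was left out; MBF1c, the 18.5 kDa protein, GLABRA2, potassium transporter 8 and snakin-1 did not, and all 5 lost it without the second unsupplied 3212 library.

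**Figure D2:**
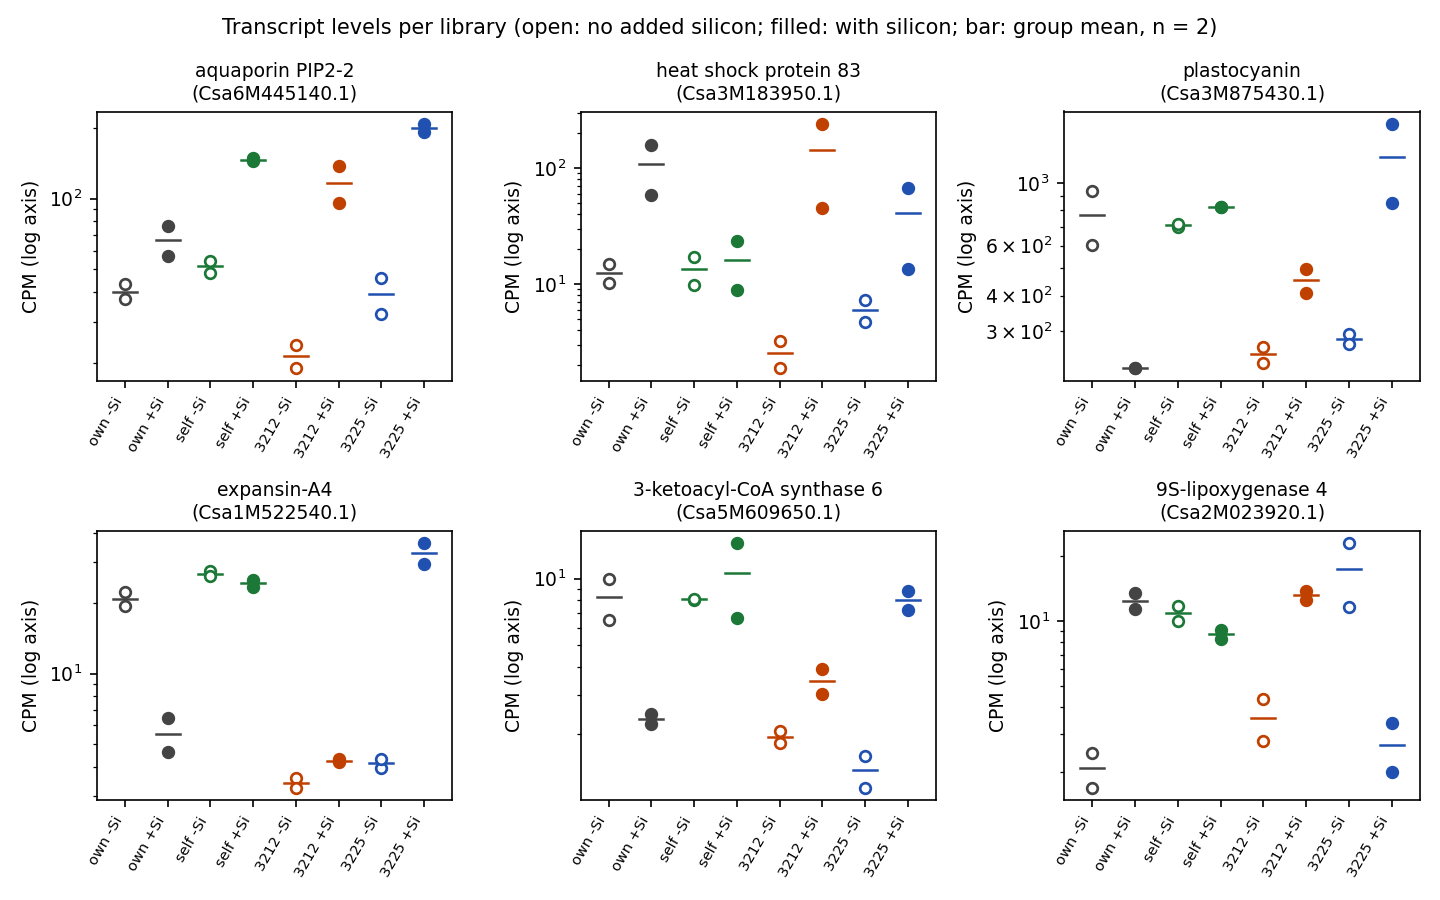
Levels of 6 transcripts in each library, as CPM on a log axis. Points are libraries and short bars are group means (n = 2); PIP2-2 lies higher with silicon than without in each of the 4 graft types.

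In ungrafted own-rooted plants photosynthesis and aquaporin transcripts were lower and many chaperones higher after silicon. The light-harvesting and photosystem list had 24 of 41 lower and 0 higher (26 and 1 adjusted over the list alone), with a median of -0.88 log2 and camera adjusted p = 1.4e-07, and adjusted p = 0.58 with an estimated correlation. Plastocyanin (Csa3M875430.1), an electron carrier between the photosystems, fell, at -1.80 ± 0.27 (adjusted p = 0.001) by edgeR, and the photosystem II gene psbY (Csa5M592810.1) at -2.30 ± 0.34 (adjusted p = 0.0011). Aquaporins had 14 of 31 lower and 1 higher (17 and 2 adjusted over the list alone), with camera adjusted p = 0.0025, and adjusted p = 0.085 with an estimated correlation. The vacuolar water channels TIP4-1 (Csa2M374630.1) and TIP1-1 (Csa3M743400.1) stood at -1.90 ± 0.29 (adjusted p = 0.0012) and -1.44 ± 0.23 (adjusted p = 0.0016). Chaperones had 31 of 150 higher and 14 lower (33 and 14 adjusted over the list alone), with camera adjusted p = 0.02, and adjusted p = 0.49 with an estimated correlation. Heat shock 70 kDa protein 17 (Csa4M617390.1) rose by 2.26 ± 0.23 (adjusted p = 0.00013), and heat shock protein 83 by 3.13 ± 0.86 (adjusted p = 0.02).

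Expansin-A4 (Csa1M522540.1), which loosens cell walls, fell in own-rooted plants, at -1.92 ± 0.20 (adjusted p = 0.00014) by edgeR, as did glutaredoxin-C6 (Csa4M646150.1), at -3.03 ± 0.29 (adjusted p = 0.00012), and 3-ketoacyl-CoA synthase 6 (Csa5M609650.1), an elongase of wax precursors, at -1.82 ± 0.37 (adjusted p = 0.0051). Linoleate 9S-lipoxygenase 4 (Csa2M023920.1), which oxidises linoleic acid, rose by 2.59 ± 0.37 (adjusted p = 0.00086), phenylalanine ammonia-lyase (Csa6M405960.1), the entry step of phenylpropanoid synthesis, by 1.94 ± 0.29 (adjusted p = 0.001), and WRKY12 (Csa2M297220.1) by 1.61 ± 0.19 (adjusted p = 0.00034). Genes of the cell cycle were higher as a list, with 42 of 155 higher and 10 lower (43 and 12 adjusted over the list alone) and camera adjusted p = 0.0017, and adjusted p = 0.62 with an estimated correlation. Ethylene genes were lower, with 23 of 91 lower and 2 higher (26 and 2 adjusted over the list alone) and camera adjusted p = 0.02, and adjusted p = 0.58 with an estimated correlation, and mineral transport genes as well, with 19 of 99 lower and 4 higher (18 and 4 adjusted over the list alone) and camera adjusted p = 0.02, and adjusted p = 0.58 with an estimated correlation. Without the second own-rooted library lacking silicon these 3 lists no longer passed, at camera adjusted p = 0.19, 0.17 and 0.17. By edgeR 4034 genes were called, 1725 higher (42.8%) and 2309 lower. With library totals as the scale, which shifts all log2 values by 0.1, edgeR had 54.2% of its calls higher. A fit of the 4 own-rooted libraries alone called 0 genes, with 3762 at an unadjusted p under 0.05. Leaving out the first or second supplied library gave 1586 or 1389, and leaving out the second library without silicon gave 3054. The supplied own-rooted libraries lay nearer the 3212-grafted mean for 91.9% of the 1478 genes. The changes here thus cannot be ascribed to silicon alone. The genes named here kept their call whichever library was left out, except that heat shock protein 83 lost it without either unsupplied library or the first supplied one.

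In self-grafted plants, where the wound of grafting is present without a foreign root, aquaporins rose after silicon as a list, and so did the seed storage genes, markers of another tissue (camera adjusted p = 0.048, and 0.53 with an estimated correlation; 0 of 15 called). PIP1-4 rose by 1.72 ± 0.17 (adjusted p = 0.0042) by edgeR and PIP2-2 by 1.51 ± 0.22 (adjusted p = 0.025). Aquaporins had 3 of 31 higher and 0 lower (7 and 0 adjusted over the list alone), with camera adjusted p = 0.00018, and adjusted p = 0.024 with an estimated correlation. Spermidine hydroxycinnamoyl transferase (Csa4M190020.1), which makes phenolamides, rose by 2.92 ± 0.43 (adjusted p = 0.025), and shikimate O-hydroxycinnamoyltransferase (Csa7M431440.1), of lignin synthesis, by 1.58 ± 0.19 (adjusted p = 0.018). The transcription factor ERF008 (Csa2M279260.1) rose by 1.49 ± 0.24 (adjusted p = 0.03). Methyltransferase PMT4 (Csa5M606620.1) fell, at -0.83 ± 0.14 (adjusted p = 0.046). Ribosomal protein genes were lower as a list, with 0 of 251 lower and 0 higher (0 and 0 adjusted over the list alone) and camera adjusted p = 0.00018, and adjusted p = 0.73 with an estimated correlation. EdgeR called 29 genes, 22 higher and 7 lower. Leaving out any of the 4 self-grafted libraries left 0 to 2 genes, and none of the 6 genes named kept its call throughout, whereas leaving out the second own-rooted library without silicon gave 551, DESeq2 515 and a fit of these 4 libraries alone 2404.

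In plants on rootstock 3212, the weak silicon absorber, chaperones were among the strongest rises. Heat shock protein 83 rose by 5.81 ± 1.02 (adjusted p = 0.043) by edgeR, heat shock cognate 70 kDa protein by 4.91 ± 0.67 (adjusted p = 0.015) and ClpB1 by 4.03 ± 0.65 (adjusted p = 0.027). The chaperone list had 4 of 150 higher and 0 lower (25 and 3 adjusted over the list alone), with camera adjusted p = 9.2e-05, and adjusted p = 0.15 with an estimated correlation. PIP2-2 rose by 2.45 ± 0.23 (adjusted p = 0.0013) and a second PIP1-4 gene (Csa5M198770.1) by 1.72 ± 0.21 (adjusted p = 0.0085). Aquaporins had 5 of 31 higher and 0 lower (6 and 0 adjusted over the list alone), with camera adjusted p = 0.019, and adjusted p = 0.13 with an estimated correlation. Cellulose synthase 7 (Csa2M070320.1), of secondary walls, rose by 2.64 ± 0.38 (adjusted p = 0.017) and laccase-11 (Csa6M445190.1), which polymerises lignin, by 1.69 ± 0.30 (adjusted p = 0.048). A pathogen-related protein (Csa7M318990.1) fell, at -2.17 ± 0.21 (adjusted p = 0.0013), and the glycine-rich RNA-binding protein blt801 (Csa2M247040.1) at -1.59 ± 0.23 (adjusted p = 0.02). Photosynthesis genes were higher as a list, median 0.84 log2, with 0 of 41 higher and 0 lower (20 and 0 adjusted over the list alone) and camera adjusted p = 6.5e-15, and adjusted p = 0.39 with an estimated correlation. Ribosomal protein genes were lower, median -0.46 log2, with 0 of 251 lower and 0 higher (71 and 2 adjusted over the list alone) and camera adjusted p = 1.8e-16, and adjusted p = 0.46 with an estimated correlation. EdgeR called 36 genes, 28 higher (77.8%) and 8 lower. With library totals as the scale 88.5% were higher, with limma on log2(RPKM + 1) 63.2% and on log2(RPKM + 0.1) 77.1%. Leaving out any of the 4 libraries left 2 to 20, leaving out the second own-rooted library without silicon gave 473, DESeq2 called 412 and a fit of these 4 libraries alone 85. Of the 9 genes named, PIP2-2 and the pathogen-related protein kept their call whichever library was left out, and the other 7 lost it without the first unsupplied library.

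In plants on rootstock 3225, the strong absorber, photosynthesis and aquaporin transcripts rose. The photosynthesis list had 29 of 41 higher and 0 lower (32 and 0 adjusted over the list alone), with a median of 1.45 log2 and camera adjusted p = 9.9e-14, and adjusted p = 0.67 with an estimated correlation. Plastocyanin rose by 2.13 ± 0.27 (adjusted p = 0.00042) by edgeR, and photosystem I subunit III (Csa1M714680.1) by 2.05 ± 0.24 (adjusted p = 0.00027). Aquaporins had 14 of 31 higher and 0 lower (16 and 1 adjusted over the list alone), with camera adjusted p = 3e-06, and adjusted p = 0.0094 with an estimated correlation. PIP2-2 rose by 2.35 ± 0.22 (adjusted p = 7.9e-05) and PIP2-1 (Csa6M445120.1) by 1.95 ± 0.17 (adjusted p = 4.5e-05). The cuticle regulator WIN1 (Csa1M340430.1) rose by 3.18 ± 0.55 (adjusted p = 0.0024) and 3-ketoacyl-CoA synthase 6 by 2.55 ± 0.39 (adjusted p = 0.0013). As a list the cuticle and wax genes did not pass, with 7 of 45 higher and 1 lower (7 and 1 adjusted over the list alone) and camera adjusted p = 0.1, and adjusted p = 0.62 with an estimated correlation. Without 8 members whose description names another function it passed, at camera adjusted p = 0.049.

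Expansin-A4 rose in 3225-grafted plants by 2.98 ± 0.20 (adjusted p = 1.5e-05) by edgeR, glutaredoxin-C6 by 2.72 ± 0.28 (adjusted p = 0.00014), and uracil phosphoribosyltransferase (Csa4M297440.1), of pyrimidine salvage, by 3.84 ± 0.28 (adjusted p = 1.7e-05). The ubiquitin ligase RHA2A (Csa5M576680.1) rose by 3.27 ± 0.24 (adjusted p = 1.7e-05), the ascorbate-recycling enzyme DHAR3 (Csa3M286050.1) by 2.27 ± 0.19 (adjusted p = 4.5e-05), and pathogenesis-related protein 5 (Csa2M264610.1) by 1.60 ± 0.20 (adjusted p = 0.00035). Lipoxygenase 4 fell, at -2.69 ± 0.36 (adjusted p = 0.00056), as did a deSI-like protein (Csa4M006490.1), at -2.37 ± 0.17 (adjusted p = 1.8e-05), the plastid division protein PDV2 (Csa2M238880.1), at -3.15 ± 0.61 (adjusted p = 0.0045), WRKY12, at -1.66 ± 0.19 (adjusted p = 0.00026), and sulfate transporter 3.1 (Csa7M387690.1), at -1.27 ± 0.18 (adjusted p = 0.00075). EdgeR called 3009 genes, 1749 higher (58.1%) and 1260 lower, but 41% were higher with library totals as the scale, which shifts log2 values by -0.14. The supplied 3225-grafted libraries lay nearer the self-grafted mean for 95.3% of the 1478 genes. The changes here thus cannot be ascribed to silicon alone. Leaving out either unsupplied library gave 1667 or 1717, leaving out the second supplied library 1039, and a fit of these 4 libraries alone 1691. Of the 17 genes named for 3225-grafted plants, 17 kept their call whichever library was left out.

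Silicon responses were then tested between graft types. Against own-rooted plants, the response of 3225-grafted plants was higher for uracil phosphoribosyltransferase by 6.61 ± 0.38 (adjusted p = 6.4e-07) by edgeR, for expansin-A4 by 4.90 ± 0.28 (adjusted p = 6.4e-07), for 3-ketoacyl-CoA synthase 6 by 4.37 ± 0.54 (adjusted p = 0.00011) and for PIP2-1 by 2.64 ± 0.24 (adjusted p = 1.2e-05). It was lower for lipoxygenase 4, at -5.28 ± 0.52 (adjusted p = 2.3e-05), and for heat shock 70 kDa protein 17, at -3.01 ± 0.32 (adjusted p = 3.6e-05). The aquaporin response was higher than in own-rooted plants in 3225-grafted plants, with 17 of 31 higher and 0 lower (18 and 0 adjusted over the list alone) and camera adjusted p = 2.2e-06, and adjusted p = 0.0087 with an estimated correlation. It was so too in self-grafted plants, with 17 of 31 higher and 0 lower (19 and 0 adjusted over the list alone) and camera adjusted p = 3.8e-06, and adjusted p = 0.0085 with an estimated correlation, and in 3212-grafted plants, with 10 of 31 higher and 0 lower (11 and 0 adjusted over the list alone) and camera adjusted p = 2.7e-05, and adjusted p = 0.02 with an estimated correlation. The seed storage list was higher too for self-grafted plants (camera adjusted p = 0.0094), but did not pass with an estimated correlation. The number of genes whose response differed from own-rooted plants was 5452 for 3225-grafted (2979 higher), 3143 for self-grafted (1757 higher) and 2176 for 3212-grafted plants (1078 higher).

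Every response difference uses supplied own-rooted or 3225-grafted plants, which lay nearer the other kind of root in the set of 1478 genes. The differences cannot be ascribed to graft type alone. With library totals as the scale, 39.4% instead of 54.6% of the 3225 differences were higher, at a shift of -0.24 log2. Without the second own-rooted library lacking silicon the counts were 5813, 2901 and 1861. Leaving out each library gave 3927 to 6704, 1082 to 5282 and 500 to 4898. For the self-grafted and 3212-grafted differences, each library but the second own-rooted one without silicon moved the count by over 1.5 times; for 3225 none did. Fits of only the 8 libraries compared gave 3290, 1982 and 518. The 3212 response was set against the 3225 response as well, the weak against the strong absorber. It was lower for RHA2A, at -3.26 ± 0.34 (adjusted p = 0.00068) by edgeR, for expansin-A4, at -2.67 ± 0.30 (adjusted p = 0.001), and for PIP2-1, at -1.32 ± 0.23 (adjusted p = 0.011), and higher for lipoxygenase 4, by 4.57 ± 0.50 (adjusted p = 0.001). Aquaporins were lower in this contrast, with 4 of 31 lower and 0 higher (8 and 1 adjusted over the list alone) and camera adjusted p = 0.014, and adjusted p = 0.19 with an estimated correlation. It held 603 genes, 138 higher (22.9%) and 465 lower, with 39.8% higher on library totals, 103 to 307 genes without 1 of its 8 libraries, each of which moved the count by over 1.5 times, 1500 without the second own-rooted library lacking silicon and 1060 by DESeq2. The call for PIP2-1 in it was lost without the first supplied 3212 library.

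Without added silicon, the graft types were compared to ask what grafting and the rootstock change on their own. Self-grafted plants had more lipoxygenase 4 transcript than own-rooted plants, by 2.39 ± 0.37 (adjusted p = 0.026) by edgeR, and more laccase-17 (Csa3M734150.1), by 1.51 ± 0.30 (adjusted p = 0.028). The seed storage list was lower in them (camera adjusted p = 0.024, and 0.55 with an estimated correlation). They had less of the seed oil-body protein oleosin (Csa5M523090.1), at -1.49 ± 0.26 (adjusted p = 0.026), and of the nodulin-26-like channel NIP2-1 (Csa3M826650.1), of the family that holds plant silicon channels, at -2.50 ± 0.63 (adjusted p = 0.036). Plants on 3212 had less expansin-A4 than own-rooted plants, at -2.61 ± 0.21 (adjusted p = 4.2e-05), less PIP1-4 (Csa5M198770.1), at -2.52 ± 0.22 (adjusted p = 6.6e-05), and less 3-ketoacyl-CoA synthase 6, at -2.09 ± 0.38 (adjusted p = 0.002), but more fatty acyl-CoA reductase 3 (Csa1M145860.1), which makes wax alcohols, by 1.67 ± 0.31 (adjusted p = 0.0023). Aquaporins on 3212 had 16 of 31 lower and 0 higher (16 and 0 adjusted over the list alone), with camera adjusted p = 2e-05, and adjusted p = 0.015 with an estimated correlation. On 3225 they had 7 of 31 lower and 0 higher (7 and 0 adjusted over the list alone), with camera adjusted p = 0.038, and adjusted p = 0.3 with an estimated correlation, and photosynthesis genes 16 of 41 lower and 0 higher (20 and 0 adjusted over the list alone), with camera adjusted p = 5.9e-05, and adjusted p = 0.92 with an estimated correlation.

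Against own-rooted plants without silicon, edgeR called 1313 genes in self-grafted (462 higher, or 35.2%, against 24.4% on library totals), 5743 in 3212-grafted and 3253 in 3225-grafted plants. A fit of only the compared groups called 0 in each, with 2535, 4591 and 2678 at an unadjusted p under 0.05. Without the second own-rooted library the counts were 54, 3614 and 2179, and without the first 5123, 7361 and 5439. Leaving out the first or second self-grafted library gave 2 or 0, the first or second 3212 library 3557 or 2504, and the second 3225 library 869. For the self-grafted comparison limma on log2(RPKM + 1) called 597 and DESeq2 2373. All 4 genes named for it lost their call without either self-grafted library, and laccase-17, oleosin and NIP2-1 also without the second own-rooted library.

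Against self-grafted plants without silicon, both rootstocks had lower photosynthesis transcripts. On 3212 the list had 22 of 41 lower and 0 higher (25 and 2 adjusted over the list alone), with camera adjusted p = 8.6e-09, and adjusted p = 0.56 with an estimated correlation, and on 3225 21 of 41 lower and 0 higher (24 and 0 adjusted over the list alone), with camera adjusted p = 2.7e-09, and adjusted p = 0.66 with an estimated correlation. On 3212, aquaporins had 13 of 31 lower and 0 higher (16 and 0 adjusted over the list alone), with camera adjusted p = 3.4e-07, and adjusted p = 0.0058 with an estimated correlation, and pathogenesis-related and resistance genes 24 of 148 lower and 3 higher (26 and 4 adjusted over the list alone), with camera adjusted p = 0.0041, and adjusted p = 0.037 with an estimated correlation. EdgeR called 2713 genes for 3212 and 2448 for 3225, of which 44.3% were higher for 3225 and 56.4% with library totals as the scale. The counts were 731 to 1203 and 500 to 1861 without 1 library, which moved them by over 1.5 times for each but the second 3225 library, 4053 and 3995 without the second own-rooted library, and 4750 for 3212 in a fit of its 4 libraries. Between the rootstocks, plants on 3212 had less cellulose synthase 7 than plants on 3225, at -2.22 ± 0.38 (adjusted p = 0.043), less lipoxygenase 4, at -2.28 ± 0.35 (adjusted p = 0.04), and less PIP1-4 (Csa5M199270.1), at -1.01 ± 0.18 (adjusted p = 0.043). They had more of a glutathione S-transferase (Csa4M303690.1), a detoxifying enzyme below the abundance limit of the naming rule, by 5.63 ± 0.70 (adjusted p = 0.014), and more of the pathogen-related protein, by 1.96 ± 0.21 (adjusted p = 0.0071). Aquaporins were lower as a list, with 1 of 31 lower and 0 higher (9 and 1 adjusted over the list alone) and camera adjusted p = 7.2e-06, and adjusted p = 0.012 with an estimated correlation. This contrast held 48 genes, 19 higher (39.6%) and 29 lower. With library totals as the scale 40.6% were higher, and with limma on log2(RPKM + 1) 50%. It held 0 to 21 genes without 1 of the 4 libraries, 639 without the second own-rooted library, 499 by DESeq2 and 5 in a fit of the 4 libraries. All 5 genes named lost their call without the second 3212 library.

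With added silicon, own-rooted plants stood below self-grafted and 3225-grafted plants in aquaporin and photosynthesis transcripts. Aquaporins had 16 of 31 higher and 0 lower (19 and 0 adjusted over the list alone) in self-grafted plants, with camera adjusted p = 9.8e-10, and adjusted p = 0.0017 with an estimated correlation, and 17 of 31 higher and 0 lower (20 and 0 adjusted over the list alone) in 3225-grafted plants, with camera adjusted p = 1.4e-08, and adjusted p = 0.0031 with an estimated correlation. Photosynthesis genes had 24 of 41 higher and 0 lower (27 and 0 adjusted over the list alone) in self-grafted plants, with camera adjusted p = 2.1e-09, and adjusted p = 0.45 with an estimated correlation, and 32 of 41 higher and 0 lower (36 and 0 adjusted over the list alone) in 3225-grafted plants, with camera adjusted p = 3.3e-16, and adjusted p = 0.65 with an estimated correlation. Self-grafted plants had more expansin-A4, by 2.13 ± 0.20 (adjusted p = 9.5e-05) by edgeR, more uracil phosphoribosyltransferase, by 3.08 ± 0.27 (adjusted p = 7.1e-05), and more of the lipid-transfer protein DIR1 (Csa3M760500.1), by 3.28 ± 0.30 (adjusted p = 8e-05). They had less heat shock cognate 70 kDa protein, at -2.78 ± 0.61 (adjusted p = 0.0087), and less heat shock factor HSF30 (Csa2M351640.1), at -2.35 ± 0.52 (adjusted p = 0.009). In the set of 1478 genes the supplied own-rooted plants lay nearer the 3212-grafted mean for 91.9% and the supplied 3225-grafted plants nearer the self-grafted mean for 95.3%. EdgeR called 3000 genes for self-grafted (56% higher) and 3769 for 3225-grafted plants (58.6% higher), against 40.9% and 34.1% higher on library totals, with shifts of -0.11 and -0.2 log2. Leaving out 1 library gave 837 to 1382 and 1508 to 2626 genes; of the 4 libraries in each contrast, only the first supplied 3225 library moved its count by less than 1.5 times. A fit of the 4 libraries compared called 4956 for self-grafted plants. The calls for heat shock cognate 70 kDa protein and HSF30 were lost without the first own-rooted library or either self-grafted one.

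Between supplied 3212-grafted and own-rooted plants edgeR called 0 genes, although 1929 had an unadjusted p under 0.05, where 848 were expected by chance. The own-rooted libraries lay nearer the 3212-grafted mean for 91.9% of the 1478 genes. DESeq2 called 222, edgeR with the replicate number as a block 41, limma on log2(RPKM + 1) 0 and a fit of the 4 libraries 1. Calls also appeared when the first 3212 library was left out. Photosynthesis genes were higher in 3212-grafted plants as a list, with a median of 1.10 log2, 0 of 41 higher and 0 lower (36 and 0 adjusted over the list alone) and camera adjusted p = 2e-27, and adjusted p = 0.41 with an estimated correlation. Cuticle and wax genes were higher as a list as well, with 0 of 45 higher and 0 lower (5 and 0 adjusted over the list alone) and camera adjusted p = 0.041, and adjusted p = 0.41 with an estimated correlation. Between 3225-grafted and self-grafted plants, both with dense bloom, edgeR called 4 genes; the 3225-grafted libraries lay nearer the self-grafted mean for 95.3% of the 1478 genes. The 4 were ferredoxin-nitrite reductase (Csa3M207890.1), of nitrate assimilation, at -1.58 ± 0.19 (adjusted p = 0.014), and a ubiquitin-conjugating enzyme E2 24 (Csa6M517350.1), at -1.10 ± 0.14 (adjusted p = 0.014), and, named after their values were seen, a gene model with no named protein (Csa7M074910.1), at -2.75 ± 0.25 (adjusted p = 0.0012), and an uncharacterized protein (Csa1M008480.1), at 2.31 ± 0.29 (adjusted p = 0.014). Of the 4, 25% were higher, against 20% of 5 on library totals and 0 of 3 with limma on log2(RPKM + 1). Only Csa7M074910.1 kept its call whichever library was left out; the others lost it without the first self-grafted library. DESeq2 called 73, the fit of the 4 libraries 8, leaving out the first or second self-grafted library 1 or 2, the first 3225 library 18 and the second own-rooted library without silicon 19.

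Plants on 3212, the line with the least bloom, were set against the dense-bloom groups with silicon. Aquaporins and defence genes were lower than in self-grafted and 3225-grafted plants as lists, and did not pass against own-rooted plants, the remaining dense-bloom group. Against own-rooted plants aquaporins had a median of 0.00 log2, 0 of 31 called and camera adjusted p = 0.81, and adjusted p = 0.89 with an estimated correlation, and the defence list a median of -0.11, 0 of 148 called and camera adjusted p = 0.22, and adjusted p = 0.41 with an estimated correlation. Against self-grafted plants aquaporins had 18 of 31 lower and 0 higher (19 and 0 adjusted over the list alone), with camera adjusted p = 4e-09, and adjusted p = 0.0022 with an estimated correlation, and pathogenesis-related and resistance genes 39 of 148 lower and 5 higher (43 and 8 adjusted over the list alone), with camera adjusted p = 0.0016, and adjusted p = 0.022 with an estimated correlation. Phloem genes were higher there (7 of 37 called higher and 2 lower, camera adjusted p = 0.048, and 0.48 with an estimated correlation). Against 3225-grafted plants aquaporins had 17 of 31 lower and 0 higher (22 and 0 adjusted over the list alone), with camera adjusted p = 5.5e-10, and adjusted p = 0.0016 with an estimated correlation, and the defence list 35 of 148 lower and 4 higher (42 and 5 adjusted over the list alone), with camera adjusted p = 0.0037, and adjusted p = 0.036 with an estimated correlation. Against 3225-grafted plants uracil phosphoribosyltransferase stood at -3.39 ± 0.27 (adjusted p = 2.5e-05) by edgeR, expansin-A4 at -2.94 ± 0.20 (adjusted p = 1.7e-05), PIP2-1 at -1.44 ± 0.17 (adjusted p = 0.00033) and pathogenesis-related protein 5 at -1.71 ± 0.20 (adjusted p = 0.00032). Lipoxygenase 4 was higher there, by 2.29 ± 0.36 (adjusted p = 0.0017), as was WRKY12, by 1.70 ± 0.19 (adjusted p = 3e-04). Against self-grafted plants heat shock protein 83 was higher by 3.15 ± 0.85 (adjusted p = 0.022), GLABRA2 by 0.85 ± 0.27 (adjusted p = 0.046) and fatty acyl-CoA reductase 3 (Csa1M145850.1) by 1.14 ± 0.29 (adjusted p = 0.017). EdgeR called 3253 genes against self-grafted and 2563 against 3225-grafted plants (38.8% higher, 52.5% on library totals), 927 to 1593 and 938 to 1436 without 1 of the 4 libraries, each of which moved the count by over 1.5 times. Without the second own-rooted library lacking silicon the count against 3225-grafted plants was 3852. Of the genes named, those against 3225-grafted plants kept their call whichever library was left out, and those against self-grafted plants all lost it without the second self-grafted library.

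The least-bloom group was then compared with the mean of the 3 dense-bloom groups. Against own-rooted plants alone edgeR called 0 genes and DESeq2 222, so the contrast was not shown for each of the 3 groups. Expansin-A4 stood at 4.25 CPM in 3212-grafted, 5.53 in own-rooted, 24.3 in self-grafted and 32.8 in 3225-grafted plants. Aquaporins were lower, with 15 of 31 lower and 0 higher (19 and 0 adjusted over the list alone), a median of -0.67 log2 and camera adjusted p = 1.8e-08, and adjusted p = 0.0028 with an estimated correlation. PIP2-7 (Csa5M623360.1) stood at -1.37 ± 0.26 (adjusted p = 0.0088) by edgeR and the nodulin-26-like channel NIP5-1 (Csa5M146190.1), of a family that carries boric acid, at -1.22 ± 0.24 (adjusted p = 0.011). Pathogenesis-related and resistance genes had 28 of 148 lower and 2 higher (36 and 6 adjusted over the list alone), with camera adjusted p = 0.0019, and adjusted p = 0.023 with an estimated correlation. The osmotin-like protein (Csa1M505400.1) stood at -1.10 ± 0.16 (adjusted p = 0.003). Expansin-A4 was lower, at -1.94 ± 0.18 (adjusted p = 0.00032), and so was the epidermis-specific glycoprotein EP1 (Csa4M627220.1), at -2.03 ± 0.36 (adjusted p = 0.0068). Higher transcripts included GLABRA2, by 0.77 ± 0.21 (adjusted p = 0.039), fatty acyl-CoA reductase 3 (Csa6M151810.1), by 3.48 ± 0.85 (adjusted p = 0.024), an E2F-type cell cycle regulator (Csa4M622220.1), by 2.41 ± 0.42 (adjusted p = 0.0068), and WRKY12, by 1.17 ± 0.14 (adjusted p = 0.0016). Chaperones were higher as a list, with 12 of 150 higher and 6 lower (12 and 6 adjusted over the list alone) and camera adjusted p = 0.026, and adjusted p = 0.56 with an estimated correlation. Part of this was present without silicon, where the labels give sparse bloom to every group. As a list aquaporins were then lower on 3212 than in each of the other graft types, and defence genes than in self-grafted plants. Expansin-A4 stood at 3.4 CPM on 3212, 26.8 in self-grafted, 20.9 in own-rooted and 4.13 in 3225-grafted plants. WRKY12 stood at 57.5, 25.5, 19.7 and 65.7 CPM in the same order. Differences present at both silicon levels cannot be tied to bloom here.

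This contrast held 1744 genes by edgeR, 788 higher and 956 lower. Of its dense-bloom groups, 3225-grafted plants lay nearer the self-grafted mean for 95.3% of the 1478 genes and own-rooted plants nearer the 3212-grafted mean for 91.9%. The self-grafted libraries helped to choose these genes and give no such share. Own-rooted and 3225-grafted plants weigh the same in the dense-bloom mean, so an exchange of their group labels would leave this contrast unchanged. For PIP2-7, WRKY12 and Csa6M151810.1 the libraries of the least-bloom and dense-bloom groups overlap, and Csa6M151810.1 lay below the abundance limit of the naming rule. Leaving out the first or second least-bloom library gave 186 or 63, the first or second own-rooted one 964 or 1161, and the second self-grafted one 871. Without the second own-rooted library lacking silicon, which is not in the contrast, it was 3014, and a fit of the 8 supplied libraries alone called 2830. Of the 9 genes named, expansin-A4 and WRKY12 kept their call whichever library was left out, and the other 7 lost it without the second 3212 library. Without that library the fatty acyl-CoA reductase gene Csa6M151810.1 stood at -0.82, the opposite direction.

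Silicon transport was followed through 7 tested genes picked by their description, of which 6 are nodulin-26-like channels. That family holds plant silicon channels but also carries boric acid, and whether these members carry silicon was not tested. The remaining one is an arsenical pump-driving ATPase-like gene, which is not a silicon carrier by name. Only pericarp was sequenced, so transport genes of the roots were not measured. The list passed the camera test in 0 of the 22 comparisons, 2 having an unadjusted p under 0.05; fry called it in 3, and camera in 1 once the ATPase-like gene was left out. In own-rooted plants NIP2-1 (Csa3M826650.1) was lower with silicon, at -2.02 ± 0.61 (adjusted p = 0.032) by edgeR, and so was NIP6-1 (Csa4M007030.1), at -1.28 ± 0.33 (adjusted p = 0.016); the NIP2-1 levels were 24.1 and 133 CPM in the libraries without silicon and 17.7 and 21 CPM with it. Both lost their call without the second library lacking silicon or without either supplied one. In self-grafted, 3212-grafted and 3225-grafted plants edgeR called 0 of the 7 for silicon, with 1 in each at an unadjusted p under 0.05, and DESeq2 called 1, in self-grafted plants. The response differed between self-grafted and own-rooted plants for 4 of the 7, all higher in self-grafted plants, by edgeR and by DESeq2. These calls did not all hold when 1 library was left out. It differed for 1 between 3225-grafted and own-rooted plants (0 to 2 without 1 library) and for 0 in the other response contrasts, with 0 at an unadjusted p under 0.05 and 0 by DESeq2, though up to 2 were called for 3212-grafted against own-rooted plants without 1 library. Without silicon NIP5-1 (Csa5M146190.1) was lower on 3212 than in own-rooted plants, at -1.45 ± 0.28 (adjusted p = 0.0027), and with silicon it was lower on 3212 than on 3225, at -1.44 ± 0.28 (adjusted p = 0.0047). NIP7-1 (Csa3M149960.1), below the abundance limit, was lower on 3212 than in self-grafted plants with silicon, at -2.61 ± 0.60 (adjusted p = 0.01). In all, edgeR called 2 of the 7 between self-grafted and own-rooted plants without silicon, 1 between 3225-grafted and self-grafted plants without silicon, 2 between 3212-grafted and self-grafted plants with silicon and 1 for least against dense bloom, and each of these counts fell to 0 without some library. They were 0, 1, 4 and 3 without the second own-rooted library lacking silicon. Between 3212-grafted and 3225-grafted plants with silicon the NIP5-1 call was lost without the second library of either group, and the NIP7-1 call without the second 3212-grafted or self-grafted one.

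The 26 lists were tested over the 22 comparisons, and 119 tests passed with the preset correlation and 17 with an estimated one. The photosynthesis list passed in 19 comparisons (11 higher, 8 lower), aquaporins in 18 (9 higher, 9 lower), mineral transport in 12, ribosomal proteins in 11, cell cycle in 9 and heat shock in 7. Ethylene genes passed in 6, cell wall and defence genes in 5 each, phenylpropanoid and lignin and sucrose and raffinose genes in 4 each, and flavonoid and jasmonate genes in 3 each. Clock and light genes and triterpene cyclases passed in 2 each, and cuticle and wax, auxin, abscisic acid, WRKY and ABC transporter genes in 1 each. Silicon transport, epidermis and trichome, redox and gibberellin genes passed in 0. With an estimated correlation aquaporins passed in 13 and defence genes in 4, and the other lists in 0. Seed storage genes, markers of another tissue, passed in 3 comparisons (2 higher, 1 lower) and phloem genes in 1. Seed storage genes were higher with silicon in self-grafted plants, with 0 of 15 higher and 0 lower (2 and 0 adjusted over the list alone) and camera adjusted p = 0.048, and adjusted p = 0.53 with an estimated correlation. Without the second own-rooted library lacking silicon that test gave adjusted p = 0.094. Their silicon response was higher in self-grafted than own-rooted plants, with 3 of 15 higher and 0 lower (4 and 0 adjusted over the list alone) and camera adjusted p = 0.0094, and adjusted p = 0.47 with an estimated correlation. They were lower in self-grafted than own-rooted plants without silicon, with 1 of 15 lower and 0 higher (1 and 0 adjusted over the list alone) and camera adjusted p = 0.024, and adjusted p = 0.55 with an estimated correlation. Phloem genes were higher on 3212 than in self-grafted plants with silicon, with 7 of 37 higher and 2 lower (8 and 2 adjusted over the list alone) and camera adjusted p = 0.048, and adjusted p = 0.48 with an estimated correlation.

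The calls were set beside the authors' deposited tables, which compare single libraries of the same number. For the silicon effect in own-rooted plants the authors' deposited tables listed 1808 and 3387 genes, of which 881 agreed in direction in both and 30 were opposite; independent lists of those sizes would share 176. Of the 881, 853 were called here in that direction. For 3212-grafted plants the authors' deposited tables listed 623 and 605 genes with 187 in both, of which 27 were called here. For 3225-grafted plants they listed 1864 and 2356 with 817 in both, of which 747 were called here. For the 0-gene contrast of supplied 3212-grafted and own-rooted plants the authors' deposited tables shared 160 genes, 93 of them higher. A table for the silicon effect in self-grafted plants was not analysed here. Of 120 count columns in the authors' comparison tables, 118 equal the counts of the library in their title. The other 2 are titled as the first own-rooted library without silicon and hold the counts of the second self-grafted library without silicon; both stand beside the first supplied 3225-grafted library, in tables not used for the comparisons here.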

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

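The tests of differences in silicon response between graft types were planned; the tests of explanations, of the exchanged labels, the kind of root, the coding length, the left-out library and the first component, were chosen only after the result was seen. The silicon response differed between graft types by the interaction test for 5452 genes in 3225-grafted against own-rooted plants, 3143 in self-grafted against own-rooted, 2176 in 3212-grafted against own-rooted and 603 in 3212-grafted against 3225-grafted plants. Between 3225-grafted and own-rooted plants the log2 difference was 6.61 for uracil phosphoribosyltransferase, 4.90 for expansin-A4, 4.37 for 3-ketoacyl-CoA synthase 6, 2.64 for PIP2-1, -3.01 for heat shock 70 kDa protein 17 and -5.28 for lipoxygenase 4. Between 3212-grafted and 3225-grafted plants it was 4.57 for lipoxygenase 4, -1.32 for PIP2-1, -2.67 for expansin-A4 and -3.26 for the ubiquitin ligase RHA2A. The aquaporin list differed in these contrasts, with camera adjusted p = 2.2e-06 for 3225-grafted, 3.8e-06 for self-grafted and 2.7e-05 for 3212-grafted against own-rooted plants (0.0087, 0.0085 and 0.02 with an estimated correlation). For 3212-grafted against 3225-grafted plants it was 0.014, but 0.19 with an estimated correlation. The seed storage list differed for self-grafted against own-rooted plants, at 0.0094, but 0.47 with an estimated correlation.

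Across genes the silicon responses of own-rooted and 3225-grafted plants ran against each other, with a Pearson correlation of -0.39 and a Spearman correlation of -0.43 (genes are not independent replicates), and of 1531 genes called in both 1499 moved in opposite directions, where 366.4 would be expected of independent lists. A candidate explanation is an exchange of group labels between supplied own-rooted and supplied 3225-grafted plants, which would change what most comparisons with them mean. The average silicon effect and the least-bloom contrast weigh both groups alike and would keep their calls. Of 1478 genes that part 3212-grafted from self-grafted plants at both silicon levels, at most 8.1% lay nearer the mean of the root kind that the label names in these groups, against 92.3% and 84% in the unsupplied groups of the same graft types. Taking out the trend with coding length left the correlation at -0.36, and leaving out the second own-rooted library without silicon gave -0.48, which argues against either as the whole cause. Of 61 genes called for silicon in the other graft types, 70.5% (95% interval 57.4 to 81.5) moved the same way in 3225-grafted plants, but 50.8% (37.7 to 63.9) in own-rooted plants. These intervals treat genes as independent, which they are not, and may be too narrow. The first share therefore argues only weakly against exchanged silicon labels in 3225-grafted plants. The second would be near 50% under either labelling and leaves such an exchange open in own-rooted plants. A shared harvest or batch stays open too, because both libraries lay on the same side of the first component in all 8 groups. The shares of the 1478 genes go with an exchange of group labels, and so do correlations of group means across genes. Supplied own-rooted plants correlated most with unsupplied 3225-grafted plants, at 0.984, and supplied 3225-grafted plants with supplied self-grafted plants, at 0.985. A response to silicon that depends on the graft type was not set against the exchange in a test, so both stay open. Of 120 count columns in the authors' tables, 2 hold another library than their title names, but 0 of the 40 titled as these supplied groups. An exchange before the tables were made would leave no trace there.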

How the results depend on the processing

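The tests added after the results were seen are edgeR with library totals as the scale, the fits without the second own-rooted library lacking silicon for contrasts that do not use it and the lists without off-name members; the others were planned. Of the 113 pairs of a named gene and a contrast, all kept direction and call with RLE size factors, without a filter and with DESeq2, all 112 that passed the stricter filter kept them under it, 110 with library totals as the scale, 110 with the replicate number as a block, 99 and 101 with limma on log2(RPKM + 1) and log2(RPKM + 0.1), and 69 of 99 in a fit of only the groups compared; the others kept direction and lost the call. Leaving out 1 library kept 590 of 766 calls, lost 175 and turned 1: fatty acyl-CoA reductase Csa6M151810.1 in least against dense bloom ranged from -0.82, without the second 3212 library, to 4.46. DESeq2 gives some genes no p, and these were not counted. The fit of only the groups compared is the full fit for the average effect and has no value of its own there. The cause was not tested for any change in this part.

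Counts of called genes moved by no more than 1.5 times in all 22 contrasts with RLE size factors, library totals as the scale and the stricter filter. Without a filter the count was 87 for silicon in self-grafted plants, 68 in 3212-grafted plants, 106 between the rootstocks without silicon and 8 between 3225-grafted and self-grafted plants with silicon. With limma on log2(RPKM + 0.1) it was 19 for silicon in self-grafted plants and 612 for self-grafted against own-rooted plants without silicon, which had 597 on log2(RPKM + 1). The labels do not say whether the replicate number stands for anything shared; deviations of equal number correlated between groups at -0.32 to 0.2 (median 0.02). With that number as a block the counts that moved were 101 for silicon in self-grafted plants, 106 between the rootstocks without silicon, and with silicon 41 for 3212-grafted against own-rooted and 10 for 3225-grafted against self-grafted plants. DESeq2 called 515, 412 and 749 for silicon in self-grafted and 3212-grafted plants and on average, 2373 for self-grafted against own-rooted plants and 499 between the rootstocks without silicon, 222 for 3212-grafted against own-rooted and 73 for 3225-grafted against self-grafted plants with silicon, and 1060 for the 3212 against the 3225 response. A fit of only the groups compared called 0, 2404, 85 and 1691 for silicon in own-rooted, self-grafted, 3212-grafted and 3225-grafted plants. It called 0 for each graft type against own-rooted plants without silicon, 4750 for 3212-grafted against self-grafted plants and 5 between the rootstocks there, 4956 for self-grafted and 1 for 3212-grafted against own-rooted plants with silicon, 8 for 3225-grafted against self-grafted plants, 2830 for least against dense bloom, and 1982, 518 and 3290 for the responses of self-grafted, 3212-grafted and 3225-grafted against own-rooted plants.

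Leaving out 1 library, the second own-rooted one without silicon included for every contrast, assumes that a lone library varies like the other groups. The counts ran from 1389 to 5690, 0 to 551, 2 to 473 and 1039 to 4424 for silicon in own-rooted, self-grafted, 3212-grafted and 3225-grafted plants, and from 57 to 1249 on average. Without silicon they ran from 0 to 5123, 2504 to 7361 and 869 to 5439 for self-grafted, 3212-grafted and 3225-grafted against own-rooted plants, 731 to 4053 and 500 to 3995 for the rootstocks against self-grafted plants, and 0 to 639 between the rootstocks. With silicon the same order gave 837 to 4312, 0 to 8, 1508 to 5161, 927 to 4687, 1 to 19 and 938 to 3852. They ran from 63 to 3014 for least against dense bloom, and for the differences in response from 1082 to 5282, 500 to 4898 and 3927 to 6704 against own-rooted plants (self-grafted, 3212, 3225) and 103 to 1500 for 3212 against 3225.

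List tests past the threshold numbered 119, and 17 with an estimated correlation, 120 with the block, 117 on log2(RPKM + 1), 111 with fry (59 shared with the 119), 127 without off-name members and 116 without the second own-rooted library lacking silicon (93 shared, 2 turned). With a minimum absolute log2 ratio of 2, the authors' tables of both library numbers shared 144, 40 and 150 genes for silicon in own-rooted, 3212-grafted and 3225-grafted plants. Without silicon they shared 43, 215 and 111 for self-grafted, 3212-grafted and 3225-grafted against own-rooted plants and 20 between the rootstocks. With silicon they shared 125, 21, 168, 177, 22 and 129 for self-grafted, 3212-grafted and 3225-grafted against own-rooted plants, 3212-grafted and 3225-grafted against self-grafted plants and between the rootstocks. On simulated data edgeR found 42% of 2-fold changes in a contrast of 2 against 2 libraries, and 61% of 1.5-fold and 98% of 2-fold changes in the average over all 16 libraries. In the simulation 2-fold changes were thus often missed in contrasts of 2 against 2. The real data hold a library that stands apart, which the simulation did not, so the real shares may differ.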

Other observations

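All tests in this part were chosen only after the results were seen. Gene ontology process terms were tested, 142 in each of 8 contrasts. With an estimated correlation 0 passed, so the adjusted p values below rest on the preset one. No term was refitted without the second unsupplied own-rooted library. Genes for the response to reactive oxygen species were higher with silicon on average, with 5 of 25 called higher and 0 lower, a median of 0.24 log2 and adjusted p = 8.9e-06 (0.15 with an estimated correlation). In 3225-grafted plants 9 of the 25 were called higher and 0 lower (adjusted p = 0.023). Genes for the response to light intensity were higher on average, with 4 of 40 called higher and 0 lower (adjusted p = 0.00016, and 0.23 with an estimated correlation). DNA-dependent DNA replication genes were higher with silicon in own-rooted plants, with 7 of 20 called higher, a median of 0.59 log2 and adjusted p = 0.0084, and lower in 3225-grafted plants, with 5 of 20 called lower, a median of -0.56 and adjusted p = 0.015 (0.76 in both with an estimated correlation). In 3212-grafted plants they were lower too, with 0 called, a median of -0.33 and adjusted p = 0.021 (0.71 with an estimated correlation). Exchanged group labels could also set own-rooted against 3225-grafted plants here. Amino acid transport genes were lower in own-rooted plants, with 9 of 22 called lower and 0 higher and adjusted p = 0.0084 (0.71 with an estimated correlation).

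Genes for the response to biotic stimulus were lower in the least-bloom than in the dense-bloom groups, with 9 of 25 called lower and 0 higher, a median of -0.75 log2 and adjusted p = 0.00021 (0.19 with an estimated correlation). Against 3225-grafted plants alone 10 of the 25 were lower, with a median of -1.06 (adjusted p = 0.00016, and 0.17 with an estimated correlation). With silicon, genes of porphyrin synthesis and of photosynthetic electron transport were higher in 3212-grafted than in own-rooted plants, with medians of 0.50 and 0.52 log2, 0 called and adjusted p = 2.1e-08 and 7.1e-09 (0.52 in both with an estimated correlation).

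The second own-rooted library without silicon stood apart from its replicate. Named after their values were seen, the homeobox gene ATHB-21 (Csa6M501990.1) was at 484 CPM in it and 0.445 CPM in its replicate, ATHB-7 (Csa3M119240.1) at 111 and 1.34 CPM, and isocitrate lyase (Csa2M420990.1), of the glyoxylate cycle, at 45.6 and 0.267 CPM. Its highest correlation with the mean of another group was 0.936, with supplied self-grafted plants, below the lowest of 0.972 between replicates elsewhere. Its correlation with its own replicate was 0.93, so it fell short of that mark for its own label too. These values therefore cannot tell whether its label was exchanged with another of the 7 groups. A sample from outside the study stays open as well. Its 10 most abundant gene models held 6.449% of its reads, within the 5.612% to 9.504% of the other libraries, which argues against a few dominant genes. An abscisic acid or water-loss response in that sample is a hypothesis: the abscisic acid list lay at percentile 98.7 of random lists of like abundance, but the jasmonate, ethylene, gibberellin and phenylpropanoid lists lay at 100 and the ribosomal and cell cycle lists at 0, so the shift may be wider than this hormone.

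For the average silicon effect the real split called 260 genes. Of 100 splits of the libraries within graft types, drawn from 648, 8 called as many, the real one included. The other 7 called 947 to 4572, which points to a structure of the samples. All 7 turned the silicon labels of own-rooted plants against those of 3225-grafted plants. The remaining 92 called at most 25, but each mixed silicon levels in a group. The splits thus cannot decide on chance.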
